A study of Sus scrofa with 6 samples.

How the data were processed

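The samples were tooth germs of 4 deciduous tooth types from miniature pig embryos of days 40, 50 and 60, each condition represented by 1 RNA, per the labels. Germs were removed under a microscope, per the labels, which do not say whether germs of several embryos were pooled. Per the labels' protocols, total RNA was purified with a kit, the fraction of small RNAs was isolated on a filter, extended with a poly(A) tail and ligated to a tag for Cy3 or Cy5 staining. Pairs of RNAs were then hybridised on 6 arrays. The scanner, the image software and the steps behind the processed values are not given in the sources used here.

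The deposited files for each array hold the mean intensity of every spot in 2 density columns on a linear scale, with no background removed; blank spots read medians of 39.2 to 273 per RNA. Values of 1000 and above were written with commas between digits, which were taken out. A deposited table holds the authors' processed log2 values, 1 per probe and array. Set against the log2 ratios computed here, these values ran as the first-named RNA over the second on all 6 arrays (r = 0.86 to 0.96 across probes), with medians of 0.01 to 0.16; how they were scaled and centred stays unknown. They served as an alternative only.

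The RNA of each density column was taken from the column heading, per the file headers, and the dye from the labels. On 5 arrays the left column holds the RNA labelled Cy3. On the array of the later molars, headings and labels disagree about this order, so the dye by column position and the exchange of its RNAs were tried as well. The title of one array gives a different day for the incisor than its other labels, and day 50 was used as in the other labels.

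Each array has 3968 spots, of which 716 are blank. A background surface was fitted through the blank spots of each array and channel (robust loess, span 0.3) and corrected with normexp at an offset of 50. Arrays were then normalised within (loess, control spots at weight 0) and between arrays (Aquantile), and the log2 values of the 4 spots of a probe were averaged. A probe counted as detected in an RNA when its mean lay more than 3 SD of the blank spots (from the median absolute deviation) above the surface, and 656 probes detected in at least 3 of 12 RNAs were tested, among them 176 of the mature pig miRNA probes. All 12 RNAs detected 222 probes, and 3 probes were detected in none. Replicate spots of a probe differed by a median SD of 0.09 to 0.15 on the log2 scale.

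With 1 RNA per condition, the log2 intensities of both channels were fitted in limma 3.58.1 (statmod 1.5.0, R 4.3.3) as tooth type plus day plus dye, with the array as a random block. The correlation within arrays was 0.83, and 5 residual degrees of freedom remained (prior 1.26). This correlation, on which the standard errors rest, was not stable over the alternatives below. It was 0.14 with median centring. On leaving out RNAs or arrays it ran from -0.34 (without the day-40 incisor and premolar array) to 0.97 (without the day-50 premolar and day-60 canine array). With 1 RNA per condition, a p-value sets a difference against the spread of single RNAs that tooth type, day and dye leave unexplained. Departures of a tooth type from the common course over days fall into that spread, along with measurement error. A p-value here says nothing about the spread between animals. Tests were moderated F or pairwise contrasts, two-sided, with Benjamini-Hochberg adjustment over the 656 probes and a threshold of 0.05. No probe showed a dye effect at this threshold (limma).

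Within each array, the log2 ratio of its RNAs was described without a test. A ratio was listed where the probe was detected in at least 1 of the 2 RNAs and the ratio was at least 2-fold, in one direction, in all 4 spots. Where a probe was not above background in one RNA, the ratio is a bound against the higher of its own level and the lowest detected level of that RNA, and is open to dye bias.

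Before the data were examined, 10 lists of miRNAs were fixed from general knowledge: let-7 family, miR-17 cluster and paralogs, epithelial, mesenchymal and skeletal, DLK1-DIO3 cluster, Hox-cluster, skeletal muscle, blood cell, endothelial and neural. Members were matched by miRNA name without species, arm and copy number, among mature pig probes and custom probes with a miR name; PN and PC probes were left out of the lists. Lists with at least 3 tested probes were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. On single arrays, a list's median was placed among 10000 random lists matched on intensity.

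The miRNAs named in the text follow a rule set at the same time. For day and for posterior against anterior germs, those past the threshold with one sign in all tooth types or days were to be named, by size; where fewer than 6 passed, the 6 with the smallest p are named as not having passed. For direct ratios, the 3 highest and 3 lowest per array that met the size rule are named, and for each list 2 to 4 members with the smallest p. Only mature pig miRNAs fall under the rule, and other probes were to be counted without a name. Naming some of those that passed is a departure from it, chosen after their values were seen.

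The alternatives were a normexp offset of 16, no background correction, median centring in place of loess, no scaling between arrays, quantile scaling, no filter on dim probes, detection in all 12 RNAs, the median of spots, no dye term, no array block, an intensity trend in the prior, day as a linear trend, and leaving out each RNA and each array in turn. For ratios they were the authors' values, a 1.5-fold rule and the mean ratio alone. Chosen after seeing the data were the dye by column position, the exchange of the RNAs on the later molar array, one background value per array and channel, and detection above the mismatch control probes.

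The procedure was tested on simulated data for 656 probes, of which 200 were changed. For day 60 against day 40, it recovered 68.8% of the 2-fold and 88.2% of the 4-fold changes over 5 runs, with a mean of 5 unchanged probes called. The simulated noise was normal, with a common correlation within arrays and no array that stood apart. Far more probes changed than were called in the data, which makes the adjusted threshold easier to reach. These shares therefore do not give the power of the real comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.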

Results

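MicroRNAs were measured in tooth germs dissected from miniature pig embryos. The germs came from 4 deciduous tooth types (incisor, canine, premolar and molar) at embryonic days 40, 50 and 60, which gives 12 conditions with 1 RNA each. The 12 RNAs were hybridised in pairs on 6 dual-colour arrays, with 4 spots for each probe. Of the 742 probes, 188 stand for mature pig miRNAs and the rest for miRNA names taken from other species or for predicted candidates. The number of probes above background ranged from 266 in the day-50 incisor to 732 in the day-50 premolar, and 656 probes were tested. On every array the left density column had more probes above background than the right, so these numbers do not describe the RNAs alone. No condition was replicated, so each test below takes the other days as replicates of a tooth type (n = 3 RNAs) or the other tooth types as replicates of a day (n = 4 RNAs), and the number of arrays limits the precision.

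The first comparison asked which miRNAs differ between tooth types. The 2 muscle-enriched miRNAs miR-133a and miR-133b were highest in the premolar germ on each of the 3 days. miR-133b stood at 10.52 ± 0.27 (SD, n = 3) in normalised log2 intensity in premolars, against 7.35 ± 0.18 in incisors, 7.83 ± 1.18 in canines and 6.48 ± 0.17 in molars. miR-133a stood at 10.08 ± 0.27 in premolars, 7.24 ± 0.17 in incisors, 7.63 ± 1.09 in canines and 6.51 ± 0.13 in molars. Among the other tooth types, the day-50 canine came closest, with 9.14 for miR-133b and 8.83 for miR-133a. In the limma fit with tooth type, day and dye, miR-133b was 12.1-fold higher in premolars than in incisors (log2 3.60 ± 0.31, SE, adjusted p = 0.00348) and miR-133a 9.3-fold (log2 3.22 ± 0.28, adjusted p = 0.00348). Against canines the log2 differences were 2.70 ± 0.38 for miR-133b and 2.46 ± 0.35 for miR-133a (adjusted p = 0.0460 for both), calls that held in 7 and 6 of 32 alternatives. miR-206, which is specific to skeletal muscle, did not pass. It read 7.28, 6.61 and 7.90 in the day-40, day-50 and day-60 premolars and 7.35 and 7.57 in the later molars, and was 1.11 ± 0.21 higher on the log2 scale in premolars than in incisors (adjusted p = 0.0885).

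**Figure D1:**
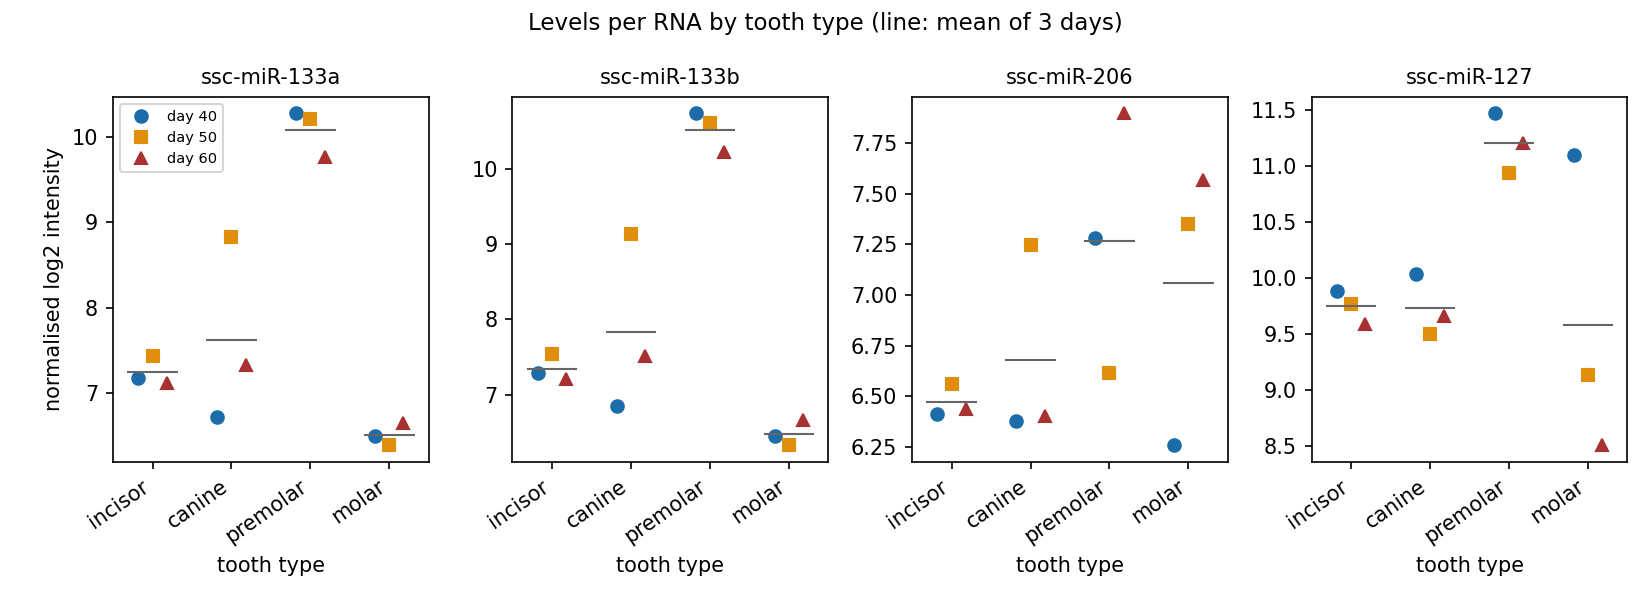
Normalised log2 intensity (vertical axis) of miR-133a, miR-133b, miR-206 and miR-127 in the 12 RNAs, by tooth type; symbols mark the day and each line the mean of 3 days. Premolar miR-133b lies between 10.22 and 10.74 and every RNA of another tooth type at or below 9.14.

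Across the 4 tooth types, 6 probes passed the F test (123 had an unadjusted p below 0.05). They were the pig probes for miR-133a and miR-133b, the 2 further probes of these names, one candidate (PC-5p-44729, adjusted p = 0.0156, highest in molars) and one probe for miR-485-3p (PN-485-3p-375, adjusted p = 0.0379). The 4 miR-133 probes share nearly all of their sequence and differ only at the ends, so they may read the same signal. The count was 0 in limma with median centring, without the array block, with dye by column and on leaving out any of 8 single RNAs, and 110 without the day-40 molar. Between single tooth types, 6 probes were higher in premolars than in incisors, and none was lower. Besides the 4 miR-133 probes they were PN-485-3p-375 (log2 0.92 ± 0.11, adjusted p = 0.0162) and PN-299-5p-13746 (log2 0.49 ± 0.06, adjusted p = 0.0179), both named for miRNAs of the imprinted DLK1-DIO3 cluster. These calls held in 15 and 10 of 33 alternatives and not without the array of the later molars (adjusted p = 0.147 and 0.246). Against canines, 5 probes were higher in premolars. The other pairs gave 2 probes for molar against incisor, 3 for molar against canine, 1 for molar against premolar and 0 for canine against incisor (88 at an unadjusted p below 0.05, limma). miR-127, a DLK1-DIO3 miRNA, stood at 11.20 ± 0.27 in premolars, 9.75 ± 0.15 in incisors and 9.73 ± 0.27 in canines. Its premolar against incisor difference of 1.30 ± 0.21 did not pass with all arrays (adjusted p = 0.0554) and passed without the array of the later molars (log2 1.40 ± 0.06, adjusted p = 0.00792). The probes outside the mature pig set were singled out after their values were seen. Without that array, miR-133b kept a premolar against incisor difference of 3.44 but not its call (adjusted p = 0.116, range 9.32e-05 to 0.999 over 32 alternatives, of which 21 kept the call).

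The second comparison set the posterior germs (premolar and molar) against the anterior ones (incisor and canine). No probe passed in limma, with a smallest adjusted p of 0.0527. At an unadjusted p below 0.05 there were 139 probes, 75 higher and 64 lower in the posterior germs. The 6 mature miRNAs with the smallest p were miR-1307 (log2 -0.49 ± 0.08), miR-133a (1.45 ± 0.26), miR-133b (1.56 ± 0.28), miR-338 (-0.17 ± 0.03), miR-185 (-0.62 ± 0.12) and miR-196b (-0.16 ± 0.03), each with an adjusted p of 0.0839. All 6 had the same sign on all 3 days. The posterior value of miR-133a and miR-133b came from premolars, since molars had the lowest levels. miR-338 and miR-196b lay near the background, with means between 6.14 and 6.41 in each tooth type.

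The lists of functionally related miRNAs that were fixed before the data were examined were tested on the same contrast. The skeletal muscle list passed in camera with a preset correlation (median log2 0.90, 6 of 8 probes higher in posterior germs, adjusted p = 0.0341, but adjusted p = 0.482 with an estimated correlation, and adjusted p = 0.204 without the later molar array). In fry, which tests whether the members move one way on balance without comparing them to other probes, its adjusted p was 0.0443. None of its probes passed over all probes and 6 passed adjusted over the list alone. Its 8 probes carry 5 distinct names, and the miR-133a and miR-133b probes that passed the F test may read the same signal. Its members with the smallest p, miR-133a and miR-133b, were followed by miR-208b (log2 -0.11 ± 0.04) and miR-206 (0.54 ± 0.19). The list mean was 8.19 to 8.35 in premolars but 6.34 to 6.57 in molars, below every incisor RNA (6.71 to 6.89). The posterior value thus came from premolars, and the call held in 14 of 34 alternatives. The Hox-cluster list also passed with the preset correlation (median log2 -0.14, 0 of 4 probes higher, adjusted p = 0.0235, but adjusted p = 0.482 with an estimated correlation). Its miR-196a (-0.18 ± 0.04) and miR-196b passed adjusted over the list alone. The Hox-cluster list kept its call without the later molar array (adjusted p = 0.0456) and had an adjusted p of 0.0421 in fry. All 4 probes were close to background, with detection in 4 or 5 of the 12 RNAs.

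The remaining lists did not pass for posterior against anterior germs. The DLK1-DIO3 list had a median of 0.05 (10 of 15 probes higher, adjusted p = 0.203), with miR-127 at 0.85 ± 0.19 and miR-299 at 0.27 ± 0.07. The let-7 family, whose members rise as tissues mature, had a median of 0.58 (adjusted p = 0.197, median 0.22 without the later molar array), with let-7c at 0.71 ± 0.33 and let-7i at 0.61 ± 0.29. The epithelial list had a median of 0.13 (adjusted p = 0.390), which turned to -0.06 with median centring, and held miR-184 (-0.14 ± 0.05) and miR-205 (0.29 ± 0.28). The mesenchymal and skeletal list had a median of -0.04, a mean of 0.02 and a test direction towards lower values (adjusted p = 0.688). When arrays were not scaled to each other, the median of all probes was 0.10, and so was that of this list. Its miR-143 stood at -0.61 ± 0.23 and its miR-34c at -0.14 ± 0.05. The miR-17 cluster list, a group that promotes proliferation, had a median of 0.01, a mean of -0.05 and a test direction towards lower values (adjusted p = 0.983), and its median turned negative (-0.04) with median centring. Its miR-92a stood at 0.45 ± 0.14 and its miR-19b at -0.87 ± 0.42. The neural list had a median of -0.04 (adjusted p = 0.390). Without scaling between arrays it turned to 0.05, still below the 0.10 of all probes there. In the neural list miR-124a (-0.22 ± 0.05) passed adjusted over the list alone and miR-129 stood at -0.09 ± 0.04. The blood cell list had a median of -0.10 (adjusted p = 0.198), with miR-142 at -0.11 ± 0.05 and miR-486 at 0.02 ± 0.05. The endothelial list had 2 probes and was not tested (log2 -0.20 ± 0.45 and 0.15 ± 0.05).

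The third comparison followed the germs from day 40 to day 60. Mature pig miRNAs gave no call for day. miR-191 and miR-425-5p, which derive from one transcript, came nearest among those with one direction. miR-191 had means of 8.31 ± 0.19 (SD, n = 4), 9.52 ± 0.52 and 9.56 ± 0.45 on days 40, 50 and 60, and was higher on day 60 than on day 40 in all 4 tooth types (log2 1.23 ± 0.21, SE, adjusted p = 0.157 in the F test). miR-425-5p had means of 6.90 ± 0.04, 7.33 ± 0.08 and 7.36 ± 0.10, again higher in 4 of 4 tooth types (log2 0.47 ± 0.08, adjusted p = 0.178). miR-1306-5p was highest on day 50 (8.04 ± 0.18, against 7.46 ± 0.19 on day 40 and 7.44 ± 0.32 on day 60, adjusted p = 0.105). miR-22-3p (0.68 ± 0.24, higher in 4 of 4 tooth types), the neuron-enriched miR-124a (-0.22 ± 0.12, higher in 0 of 4) and miR-1307 (-0.42 ± 0.20, higher in 0 of 4) each had an adjusted p of 0.215. The sign for miR-1306-5p between days 60 and 40 turned from -0.16 to 0.29 without scaling between arrays, which moved the median of all probes to 0.19.

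**Figure D2:**
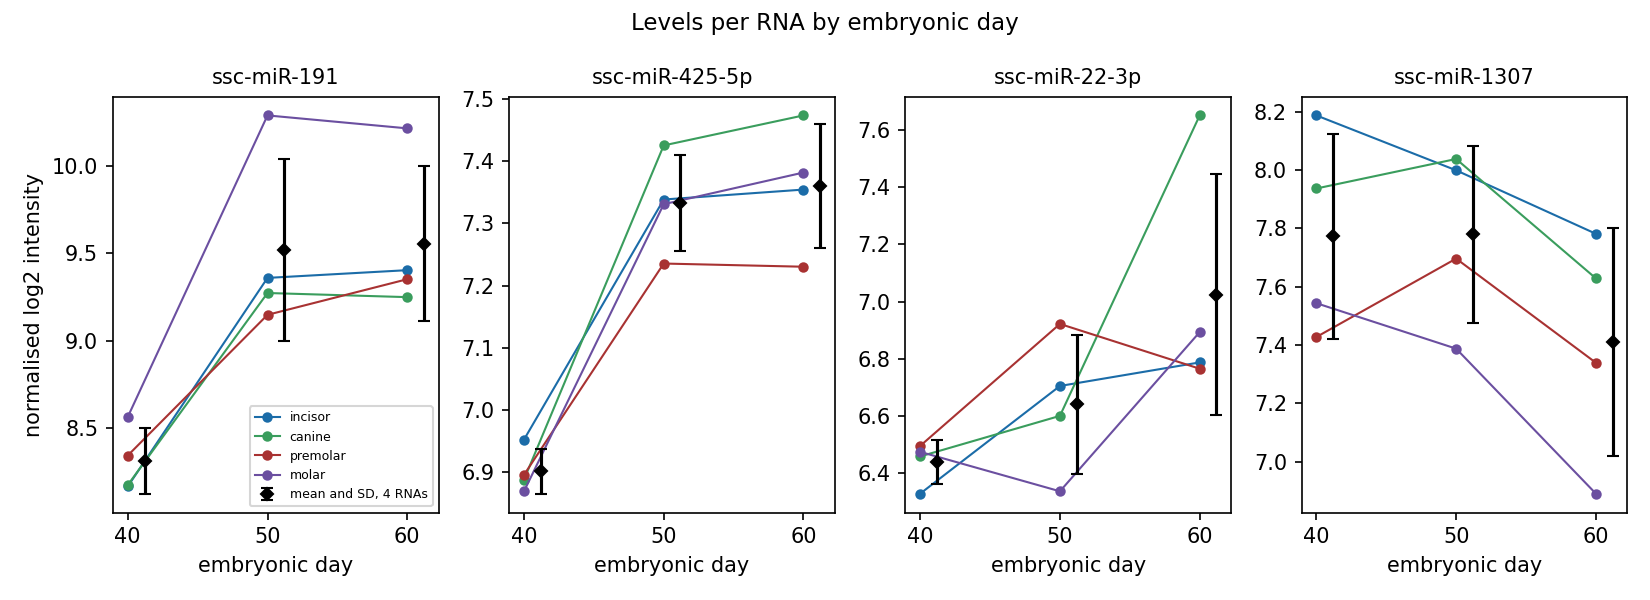
Normalised log2 intensity (vertical axis) of miR-191, miR-425-5p, miR-22-3p and miR-1307 at embryonic days 40, 50 and 60, 1 line per tooth type; black symbols give the mean and SD of 4 RNAs. miR-191 averages 8.31 on day 40 and 9.56 on day 60.

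In the F test over the 3 days, 0 of 656 probes passed in limma (102 at an unadjusted p below 0.05, smallest adjusted p = 0.100). Between days 60 and 40, 5 predicted candidates passed and each fell: PC-3p-48957 (log2 -2.68 ± 0.30), PC-3p-30694 (-2.60 ± 0.35), PC-5p-43899 (-2.23 ± 0.25), PC-5p-44729 (-1.56 ± 0.20) and PC-371-5p-22929 (-0.97 ± 0.14), with adjusted p from 0.0323 to 0.0453. These candidates were named after their values were seen. PC-3p-48957, PC-5p-43899 and PC-5p-44729 were also lower on day 50 than on day 40 (adjusted p = 0.0377), and 0 probes differed between days 60 and 50 (93 at an unadjusted p below 0.05, limma). Without the array of the later molars, 14 probes passed between days 60 and 40, 13 of them lower, and the higher one was miR-191 (log2 1.09 ± 0.13, adjusted p = 0.0434). All day-40 RNAs lay on 2 arrays that held no later day, so day 40 and array cannot be told apart, and without scaling between arrays 0 probes passed (limma).

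By day, none of the 9 tested lists passed in camera. The let-7 family had the largest median (log2 1.29, 7 of 8 probes higher on day 60, adjusted p = 0.173, and adjusted p = 0.996 with an estimated correlation), led by let-7c (adjusted p = 0.621) and let-7e (1.29 ± 0.76). That median was 0.56 without the later molar array. The epithelial list had a median of 0.30 (9 of 11 higher, adjusted p = 0.250, median 0.17 without that array) and the mesenchymal and skeletal list 0.09 (16 of 24 higher, adjusted p = 0.222), with miR-199a-3p at 1.14 ± 0.47. The skeletal muscle list had a median of 0.20 (adjusted p = 0.823) and the blood cell list 0.03 (adjusted p = 0.956). The miR-17 cluster list had a median of -0.01 and a mean of -0.07 with a test direction towards higher values (adjusted p = 0.956), and the neural list a median of 0.01 and a mean of 0.03 with a direction towards lower values (adjusted p = 0.995). The DLK1-DIO3 list had a median of -0.08 (adjusted p = 0.569) and the Hox-cluster list -0.04 (adjusted p = 0.956). Without scaling between arrays the miR-17 cluster, DLK1-DIO3 and Hox-cluster medians turned positive, to 0.16, 0.11 and 0.09. The median of all probes moved to 0.19 there, so these lists still lay below it.

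The fourth account is of the pairs of RNAs that shared an array, where ratios are free of differences between arrays. Each pair was measured once, so these are sizes with no test. On the day-40 array, premolar over incisor, the premolar had 8.58-fold more miR-133a, 3.01-fold more miR-127 and still more miR-133b (log2 ratio 3.46). On the day-60 array of the same tooth types, miR-133b was 8.05-fold, miR-133a 6.27-fold and miR-504 4.19-fold higher in the premolar. Probes that met the size rule numbered 18 higher and 4 lower on the day-40 array and 25 higher and 2 lower on the day-60 array. Both arrays shared 9 higher probes, namely 4 miR-133 probes, miR-127, miR-504 and 3 PN probes, and none went opposite ways. The 1 shared lower probe, miR-218-5p-18206, was singled out after its values were seen; it read lower in the right density column on every array, and the premolar lay in that column on both of these. The skeletal muscle list had median log2 ratios of 1.61 and 1.90 on these arrays, both at the 100th percentile of 10000 random lists, and the DLK1-DIO3 list 0.27 (100th percentile) and 0.20 (percentile 99.9). The miR-133 probes of the muscle list may read the same signal and the DLK1-DIO3 miRNAs share a cluster, so members of these lists are not independent. Random lists matched on intensity do not keep such ties, and far percentiles arose for other lists too. On the day-50 incisor and canine array the miR-17 cluster list lay at percentile 0.12 and the mesenchymal and skeletal list at 99.06, while the epithelial list lay at 6.92.

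The other arrays held single pairs. The day-60 canine had more miR-181c (4.04-fold), miR-181b (3.66-fold) and miR-181a (3.47-fold) than the day-50 premolar, which had 8.51-fold more miR-133b, 7.33-fold more miR-133a and 3.58-fold more miR-574. The day-40 molar had more miR-504 (3.71-fold), miR-339 (2.62-fold) and miR-345-5p (2.55-fold) than the day-40 canine, which had more miR-19b (3.46-fold), a member of the miR-17 cluster group, and miR-1308 (2.77-fold). The day-50 incisor exceeded the day-50 canine in miR-195 (13.3-fold) and miR-16 (10.7-fold), which share a seed sequence and restrain cell-cycle genes, and in miR-130a (7.90-fold). The day-50 canine had 3.01-fold more miR-133b, 2.91-fold more of the epithelial miR-205 and at least 2.82-fold more miR-19a, which was not above background in the incisor. The day-60 molar had 5.23-fold more miR-192, at least 2.45-fold more miR-335 (not above background on day 50) and 2.27-fold more of the hypoxia-induced miR-210 than the day-50 molar. The day-50 molar had 2.12-fold more miR-1306-5p and at least 1.54-fold more miR-224, which was not above background on day 60. The day-50 molar lay in the left density column, where miR-224 read higher than in the right on every array. The molar days were taken from the column headings, and exchanging these RNAs would turn the direction of every ratio between them. In all, 174 ratios met the rule, 117 higher in the first-named RNA and 57 lower, of which 37 and 18 were mature pig miRNAs. The largest number was on the day-50 incisor and canine array (35 and 21) and the smallest on the later molar array (7 and 4); the canine and premolar array had 17 and 13 and the day-40 molar and canine array 15 and 13. Most of these sizes depended on the processing. In the authors' values the log2 ratio of miR-133b was -3.97 in place of -3.09 on the canine and premolar array and 4.85 in place of 3.46 on the day-40 premolar and incisor array, and that of miR-504 on the day-60 array was 3.02 in place of 2.07. No dye was swapped, so these ratios hold any dye bias.

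**Figure D3:**
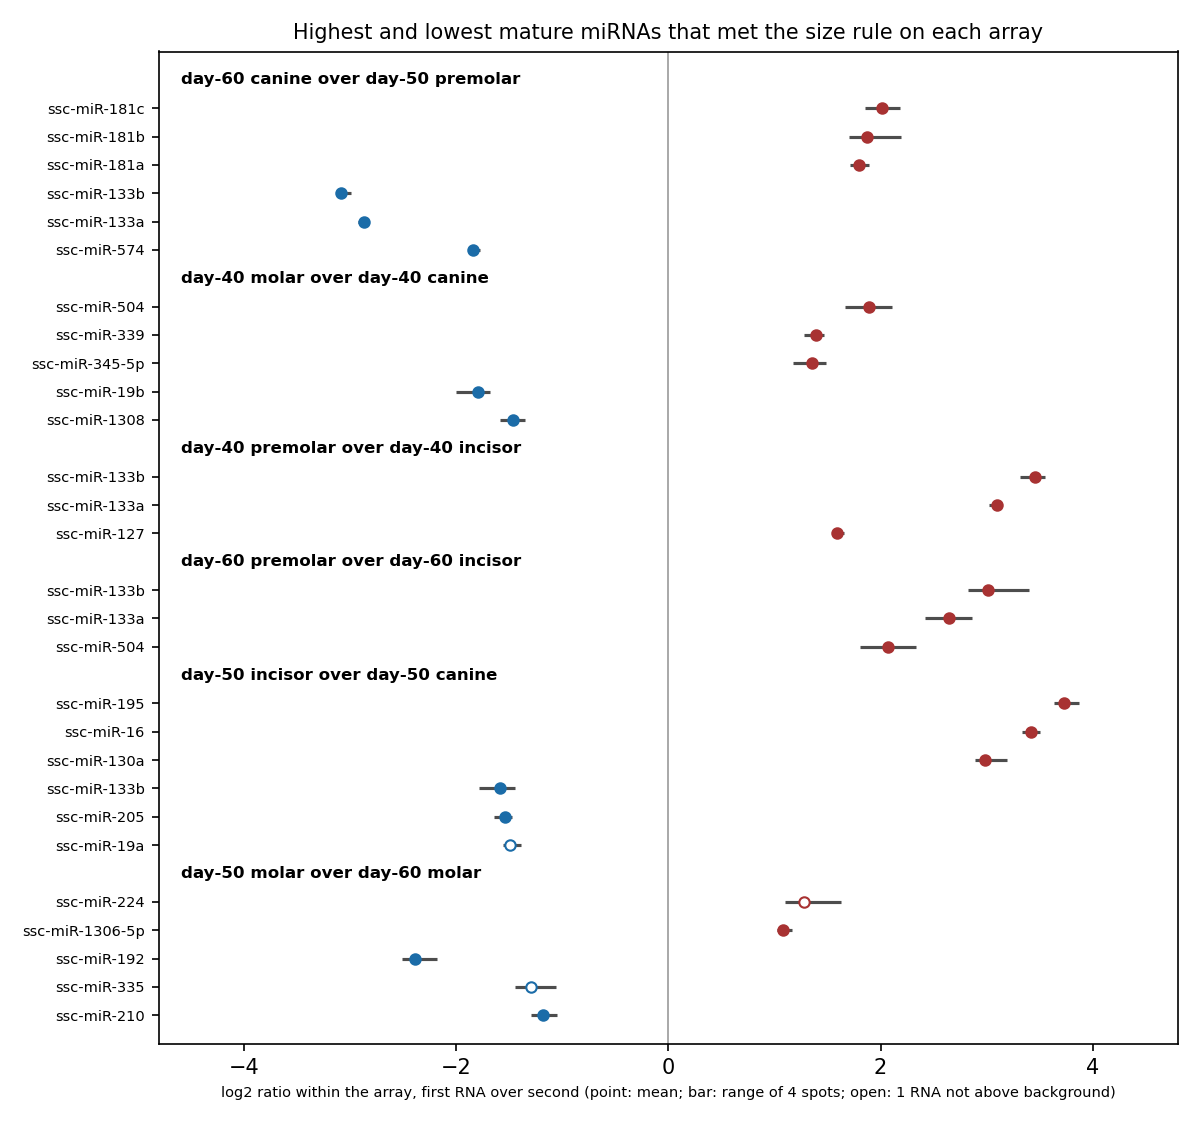
Log2 ratio of the first-named over the second-named RNA (horizontal axis) for up to 3 highest and 3 lowest mature miRNAs on each array that met the size rule. Points are means, bars the range of 4 spots, and open points mark a miRNA not above background in 1 of the 2 RNAs; miR-133b reaches 3.46 for the day-40 premolar over incisor.

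The molar RNAs of days 50 and 60, which shared an array, stood apart from the other 10. Their let-7 levels were far higher: let-7a read 12.94 and 13.10 on days 50 and 60, against 7.54 to 8.999 elsewhere, and let-7f read 12.17 on day 60 against 6.51 to 7.69 in the RNAs of other arrays. The let-7 list exceeded its mean in the other RNAs by a median of 3.45 on the log2 scale, with 7 of 8 probes higher. miR-16 (9.94 and 10.14), miR-195 (7.22 and 7.38) and miR-130a (8.11 and 8.36) read far lower than in most other RNAs, where miR-16 was at 13.53 to 14.63 except in the day-50 canine (10.68). In that canine RNA miR-195 (6.90) and miR-130a (9.40) were low too, while let-7a (8.65) was not raised. Both later molar RNAs lay outside the range of the other 10 for 273 probes, 136 of them higher, while the same count for the other arrays was between 24 and 64. Their median correlation with RNAs on other arrays was 0.70, against 0.89 to 0.96 for the other 10 RNAs. With no later molar RNA on another array, molar and array cannot be told apart here.

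**Figure D4:**
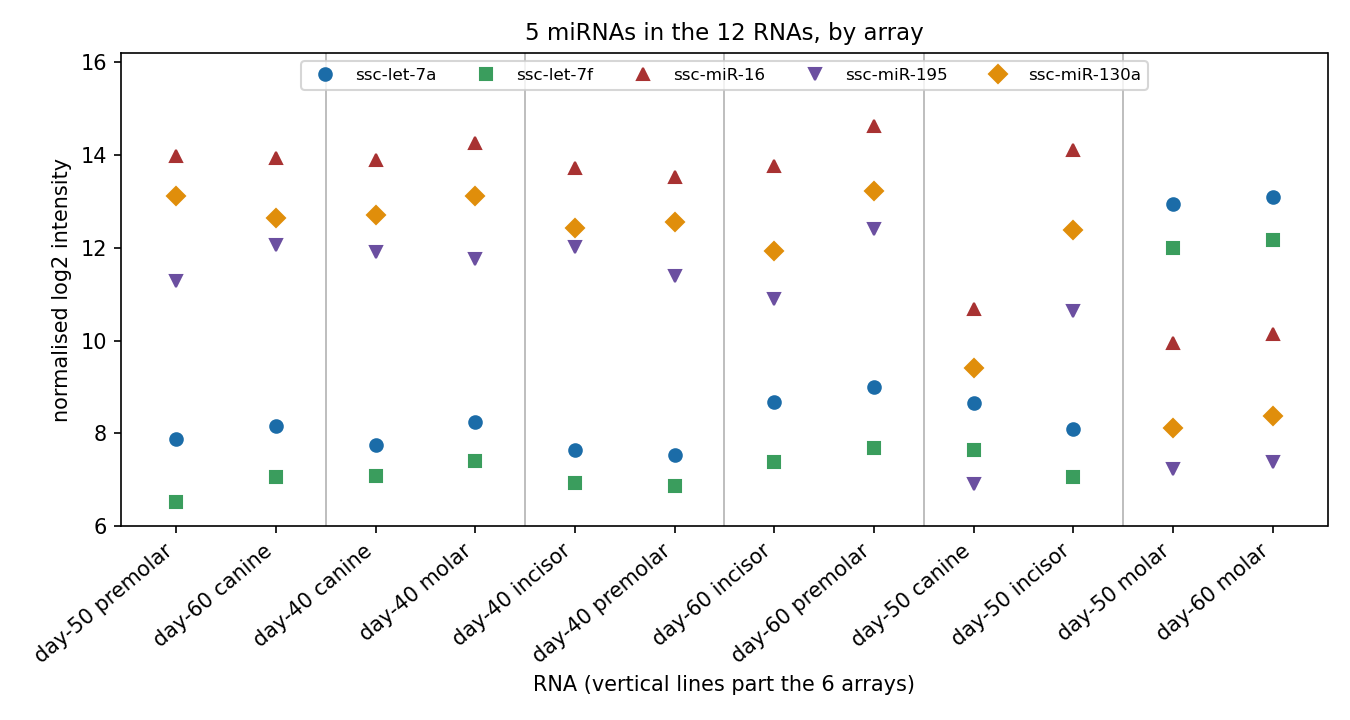
Normalised log2 intensity (vertical axis) of let-7a, let-7f, miR-16, miR-195 and miR-130a in the 12 RNAs, ordered by array with vertical lines between arrays. The later molar RNAs have let-7a at 12.94 and 13.10, and the other 10 RNAs have it between 7.54 and 8.999.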

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

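The tests of normalisation, of a molar property at day 40, of a later change in molar germs, of dye or density column, of skeletal muscle, of G content among the candidates and of array rather than day were chosen only after the result was seen; those of hybridisation stringency, of G content of any probe and of other splits were not, but their reading over all control pairs and with a standard error was.

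A first pattern is the distance of the later molar RNAs from the rest, which is clearest for let-7: on day 60 the molar lay above the other tooth types (list mean 10.55, next 7.75), a gap that made up 0.843 of the whole range. The normalisation does not account for it, since intensities as given kept 131% of the let-7 excess, and neither does a molar trait already present on day 40, when the molar had a let-7 mean of 7.38, within the 7.02 to 7.75 of the other tooth types. Lower hybridisation stringency stays open, because the spiked controls go opposite ways: of 10 mismatch over perfect match ratios (5 control pairs in 2 columns), 2 lay above the highest other array by more than 2 standard errors and 2 below it, the lowest by -1.38 (log2). One ratio below was set beforehand to exclude it, which a measure that contradicts itself by more than its spot errors does not bear out. A change in molar germs between days 40 and 50 stays open as well, because 0 other arrays held a later molar RNA, so array and tissue cannot be told apart. Both may act together. A later molar RNA paired with a premolar RNA on one array would take the array out of the comparison. With 1 RNA per condition it would still not tell a change in molar germs from a trait of the single RNA.

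A second pattern is the high miR-133a and miR-133b of premolars. On day 60 the mean of the skeletal muscle list in the premolar (8.19, next 6.82) lay above the other tooth types by 0.845 of the range. Dye or density column is excluded as the cause, because the smallest gap of a premolar RNA over the incisor and canine RNAs of the same column was 1.37 (log2). Skeletal muscle in the premolar samples is a candidate source that the values leave open. From the muscle list fixed beforehand, miR-206 was higher by 1.11 ± 0.21 in premolars than in incisors but exceeded both incisor and canine on 2 of 3 days only. The exception is day 50, when the canine had raised miR-206 (7.25) along with its raised miR-133. A second miR-206 probe lay near the floor with no premolar excess (6.01 to 6.24, incisors up to 6.28). The 2 miR-1 probes of the list were detected in at most 2 of the 12 RNAs. A PN probe named for miR-1 (PN-1-3p-13186), outside the list, read 6.18 to 7.83 over the RNAs of other arrays. It read 7.17 and 7.31 in the later molars. It was not among the probes called for premolars against incisors or canines (limma), and its premolar levels are not given here. A regulation of miR-133 within premolar germs was not tested.

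A further pattern is the fall of 5 candidate probes after day 40. Weaker stringency on the day-40 arrays needs both arrays above the others. By more than 2 standard errors, both lay above in 0 of 10 ratios and 1 of them in 3. A day-40 array lay below the highest other array in 7 (lowest -4.49), which was set beforehand to exclude the explanation. These ratios argue against weaker stringency shared by both day-40 arrays. The controls were not uniform within an array, however: in the left column the array of the day-40 canine and molar lay above in 2 ratios and below in 2. The later molar array lay above the others in 2 ratios, both in the right column, while its explanation was set to need both columns. G content of any probe stays open: the rank correlation of the G fraction with the day 60 minus day 40 difference was 0.0038 (standard error 0.074) over 176 mature miRNA probes, few of them G-rich, but -0.324 over the 73 probes other than candidates that reach the candidates' median G content. Among the 140 tested candidates the correlation was -0.559 (-0.557 given probe length and -0.394 given mean level), so the fall may belong to G-rich candidate probes in general (the 5 have a median of 50% G) and not to single miRNAs. Array rather than day stays open, since 0 day-40 RNAs shared an array with a later day.

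Other groups of 4 RNAs held 1 RNA far from the rest. On day 40 the premolar had a DLK1-DIO3 list mean of 7.20 with the next at 6.77 (0.934 of the range). On day 60 the molar had miR-191 at 10.22 with the next at 9.40 (0.840 of the range), and the canine had miR-22-3p at 7.65 with the next at 6.89 (0.855 of the range). Of 60 groups examined 5 gave such a gap, where chance gives about 3. The 4 control probes for 5S ribosomal RNA, which no comparison used, were above the blank spots in all 12 RNAs, with lowest net intensities of 2387, 4979, 1069 and 10610.

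Other splits of the same RNAs were counted for each test. By tooth type the real split gave 6 probes and 2 of 100 splits gave as many, a share under 0.05, although the highest other split gave 19. Most of these 6 probes were miR-133 probes that share nearly all of their sequence. The splits did not keep the pairing of RNAs on arrays, and the shares were not adjusted for the number of comparisons, so they cannot exclude chance. Between days 60 and 40 the real split gave 5 probes, 1 of 35 splits gave as many, and the highest other gave 0. That is the smallest share possible for these 8 RNAs, and it does not separate day from the arrays they lay on. For day 50 against 40 the share was not under 0.05 (3 probes, 3 of 35 splits, highest other 20). For day overall (highest other 49), posterior against anterior germs (highest other 4) and day 60 against 50 (highest other 12) the real count was 0, so all 100, 100 and 35 splits reach it and decide nothing. Splits that call as many as 49 probes point to a structure of the samples. Whether it lies in the later molar RNAs is open: the splits with 49 and 19 calls gave these RNAs one label, and such splits had calls in 6 of 37 by day and 3 of 18 by tooth type, against 16 of 63 and 7 of 82 of the others. Pairs of tooth types have 10 splits, too few for a share under 0.05: premolar and incisor gave 6 probes (highest other 1), premolar and canine 5 (highest other 2), molar and incisor 2 (1), molar and canine 3 (5), molar and premolar 1 (2) and canine and incisor 0 (0).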

How the results depend on the processing

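The dye by column position, the exchange of the later molar RNAs, one background per array and detection above mismatch controls were chosen after seeing the data. No call turned into a call of the opposite direction. miR-133b was higher in premolars than in incisors by 2.83 to 5.30 (log2) over 32 alternatives, of which 21 kept the call; against canines 7 of 32 kept it (6 of 32 for miR-133a), and no probe was called there with quantile scaling, the median of spots or no dye term. No paired analysis was possible because the labels give every array replicate 1 and name no animal or litter that RNAs share; the arrays entered the fit as a block. Dim probes limit all counts: 222 of 656 tested probes were detected in all 12 RNAs. Over all alternatives, tests of probes stayed on their side of the threshold 733 times, lost the call 445 times and gained one 19 times; for lists this was 566, 31 and 19. The sizes of named direct ratios moved by more than the spread of their spots 87 times and stayed within it 25 times, with no change of sign. For the changes below, the cause was not tested.

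For day overall (0 probes), the count was 3 with offset 16, 1 without background correction, 2 with the median of spots, 9 without dye and 22 without the array block. For day 60 against day 40 (5), it was 9 with median centring, 0 without scaling between arrays, 8 without filter, 2 with detection in all RNAs, 10 with the median of spots, 14 without dye, 26 without the block, 0 with an intensity trend, 0 with a linear trend, 0 with the molar RNAs exchanged and 3 with detection above mismatch controls. For tooth type (6), it was 1 without background correction, 0 with median centring, 33 with detection in all RNAs, 0 without the block, 17 with an intensity trend, 0 with dye by column and 27 with detection above mismatch controls. For posterior against anterior germs (0), it was 3 with offset 16, 1 without background correction, 9 without scaling, 4 with quantile scaling, 4 with detection in all RNAs, 1 without dye, 28 with an intensity trend and 22 with detection above mismatch controls. The median of all probes moved to 0.19 for day 60 against day 40 and to 0.10 for posterior against anterior germs without scaling between arrays.

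Of the lists by day (0), 1 passed with median centring and 1 with dye by column, the let-7 family (adjusted p = 0.0107 and 0.0394, range 0.00938 to 0.996). Of the lists by tooth class (2), the number stayed 2 without the array block, where let-7 (adjusted p = 0.0170) replaced skeletal muscle (adjusted p = 0.175); 1 passed without background correction, 1 with median centring (let-7 in place of the others, adjusted p = 0.00065), 0 without filter, 0 with detection in all RNAs, 1 without dye, 0 with an estimated correlation, 1 with dye by column, 1 with one background per array and 1 with detection above mismatch controls. Of direct ratios (174), 273 met the rule with median centring and 301 at 1.5-fold. The authors' values hold 1 value per probe and array, so the rule on single spots could not be applied to them. Without it 585 of the authors' values were counted, against 200 ratios here on the mean ratio alone.

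Leaving out each RNA or array gave 0 to 15 probes for day, 0 to 26 for day 60 against day 40, 0 to 110 for tooth type, 0 to 122 for posterior against anterior germs, 0 to 1 lists by day and 0 to 3 lists by tooth class. For day 60 against day 40, the count without the day-40, day-50 and day-60 RNA was 1, 0 and 1 (incisor), 1, 3 and 0 (canine), 17, 15 and 1 (premolar) and 26, 3 and 0 (molar). For day overall it was 15 without the day-40 molar, 10 without the day-40 premolar, 2 without the day-50 molar and 1 without each of the day-60 incisor, day-40 canine, day-50 canine and day-60 premolar. For tooth type it was 0, 0 and 0 (incisor), 5, 5 and 0 (canine), 0, 1 and 0 (premolar) and 110, 0 and 0 (molar), and for posterior against anterior germs 122 without the day-40 molar, 9 without the day-50 canine and 1 without the day-50 premolar. A list by day, the let-7 family, passed without the day-40 canine, the day-60 canine, the day-40 premolar or the day-50 molar. Without the day-40 molar, all molar RNAs lie on one array.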

Other observations

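The test of a shared rise of DLK1-DIO3 miRNAs was chosen only after the result was seen.

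The DLK1-DIO3 region expresses one of the largest miRNA clusters of mammals from the maternal chromosome. Taking the tested probes that carry a name from the DLK1-DIO3 list, PN probes included (68 probes, 53 of them PN probes), 52 were higher in premolars than in incisors, and 32 were higher on all 3 days against 1 lower on all 3 days; over all tested probes 13.6% were higher on all 3 days. The median difference was 0.09 on the log2 scale, against -0.0046 over all tested probes, so most members differ little, while miR-127 differed by 1.30 ± 0.21. In camera with an estimated correlation this list had p = 0.00774 for premolar minus incisor, which partly restates the members that prompted it. Over the 48 PN probes whose rise had not been seen, 33 were higher, with a median of 0.04. In camera with an estimated correlation these did not pass (p = 0.0560). With the preset correlation camera gave p = 8.68e-05, so the outcome rests on the correlation assumed. The bound set for a shared rise used the estimated correlation and was missed, but a list without its called members cannot exclude one. A shared rise of the cluster in premolar germs stays open as a hypothesis that may merit a test in replicated germs.

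miR-16, miR-195 and miR-130a were low in 3 RNAs, the day-50 canine and the day-50 and day-60 molars. The molars shared an array, and no tooth type or day is common to all 3. The level of miR-195 was 6.90, 7.22 and 7.38 in these RNAs and 10.63 to 12.41 in the other 9. miR-504 was highest in the day-40 molar (9.55) and in the premolars (8.09, 8.02 and 8.92), and lay between 6.85 and 6.87 in the 3 incisors. miR-192 was at 8.51 in the day-60 molar and between 6.12 and 6.46 in the other 11 RNAs. If the later molar RNAs were exchanged, the value of 8.51 would belong to the day-50 molar.

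One further probe, miR-218-5p-18206, singled out after its values were seen, separated the density columns: it averaged 8.90 ± 0.74 (SD) over the left columns and 6.21 ± 0.58 over the right columns, without overlap. The only other such probe was miR-224, where chance gives 1.42 among 656 probes. In limma 0 probes differed by density column at an adjusted p below 0.05, so a column effect on the levels of single probes is not shown. Detection did differ, with more probes above background in the left column of every array.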
